A study of Homo sapiens with 9 samples.

How the data were processed

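RNA was measured in THP-1 cells, an established human acute monocytic leukemia line, after 72 h in 1 of 3 conditions. The conditions were vehicle alone (phosphate-buffered saline, 2% v/v), interferon gamma (IFN-γ, 50 ng/ml) with vehicle, and IFN-γ (50 ng/ml) with trans-4-hydroxy-L-proline (40 mM). Each condition had 3 libraries, 9 in all, and the labels do not say whether the 3 came from separate cultures, so the tests measure the spread between these libraries. From 500 ng of total RNA per sample the authors made 3′ mRNA libraries (QuantSeq FWD), in which reads come from transcript ends.

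The authors deposited 1 table of TPM, transcript abundances scaled to a fixed total, for 60623 Ensembl genes, in which each library sums to 1000000 within 1 TPM. The submitters' notes list bcl2fastq, FastQC, Trim Galore 0.6.4, STAR 2.6.1d and featureCounts 1.6.4 on GRCh38. The program that computed TPM, its annotation and the use of strand in counting are not given in the sources used here. TPM keep no read totals, so the depth of each library is unknown and no interval or detection floor that needs it is given. A value of 0 may be a failed estimate as well as a lack of RNA, so such genes are described as listed at 0. Coordinates come from GENCODE release 29, in which 58516 of the 60623 identifiers (96.52%) had a gene.

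The fit designed before the data were examined used limma 3.58.1 in R 4.3.3 on log2(TPM + 1) of the deposited values, with the 3 groups and all 9 libraries in 1 model and an intensity trend. It kept genes with at least 1 TPM in at least 3 libraries and used two-sided moderated tests. Adjustment was by Benjamini-Hochberg over the genes tested, and genes were called at an adjusted p under 0.05. The comparisons were IFN-γ with vehicle, hydroxyproline with IFN-γ against IFN-γ, and hydroxyproline with IFN-γ against vehicle. The alternatives, the lists and the rule for named genes were fixed at the same time.

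In 2 libraries, vehicle 1 and IFN-γ 1, the gene MT-ATP6 took most of the total, which left the other genes at a fraction of the values of their group. A rescaling by median-of-ratios factors was among the alternatives fixed beforehand, and was computed here over the 10596 genes above 0 in all 9 libraries. Values are given on that scale ("rescaled TPM") unless the deposited scale is named, with the same filter, transformation and test. The choice to lead with this alternative was made after the data were seen. The numbers of genes and lists called by the designed fit stand beside the rescaled ones. Counts of list members are those after rescaling unless the designed fit is named. Fold changes are log2 differences of means of log2(TPM + 1), with the standard error of the fit (SE), and understate the change of genes near 0. Group levels are mean rescaled TPM ± SD over 3 libraries.

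Of 31 gene lists, 26 had at least 5 tested members and were tested. All 730 genes on them were found, 11 through renamed symbols. The test was camera of limma with a preset correlation of 0.01, which asks whether a list moved against the other genes, with Benjamini-Hochberg adjustment over the 26 lists. It was run beside camera with an estimated correlation and fry, whose directional p asks whether the genes of a list moved on balance in 1 direction and whose mixed p whether they changed in either direction. For each list the number of members called over all genes and the number adjusted over the list alone are given. The remaining 5 lists are markers of other cell types and are described by gene.

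The named genes were the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, 17 genes fixed in advance, and up to 4 members with the smallest p of each list. A gene outside this rule is named only where it completes a small count or shows a listed exception, and was then chosen after its values were seen. Some genes that the rule names are not reported here. The covariance of the hydroxyproline effect with the IFN-γ effect across genes was compared with 100 simulations of unchanged groups, since both comparisons share the IFN-γ libraries. The procedure was tested on simulated data with known changes.

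Alternatives to pseudocount, filter, scaling, trend, set of libraries and replicate block were computed, each library was left out in turn, and other splits of the libraries were counted. Added after the data were seen were a scaling without mitochondrial genes, the omission of vehicle 1 and IFN-γ 1 together, the combination of each alternative with the rescaled values, and a correction for transcript length and GC content. Tests for whole read counts were planned only if the values held whole reads, which they did not. No sample or column of values was left out.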

Results

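Gene expression was measured in 9 libraries of THP-1 cells, 3 with vehicle, 3 with IFN-γ and 3 with IFN-γ and hydroxyproline, each after 72 h. The series asks how IFN-γ and hydroxyproline affect gene expression in these cells. IFN-γ is the main macrophage-activating cytokine of T and NK cells, and hydroxyproline is a modified amino acid released when collagen is broken down. Depth is unknown, since TPM keep no read totals. Of the deposited total, mitochondrial genes took 52.0% to 60.9% in 7 libraries, most of it listed under MT-ND4L (44.6% to 52.0%). In the other libraries, vehicle 1 and IFN-γ 1, they took 91.6% and 87.1%, with MT-ATP6 alone at 788863 and 723569 TPM. MT-ATP6 was listed at 0 in each of the other 7. These 2 libraries had 4914 and 7038 genes at 1 TPM or more, against 10026 to 10805 in the rest. Their median-of-ratios factors were 0.235 and 0.454, against 1.17 to 1.66.

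**Figure D1:**
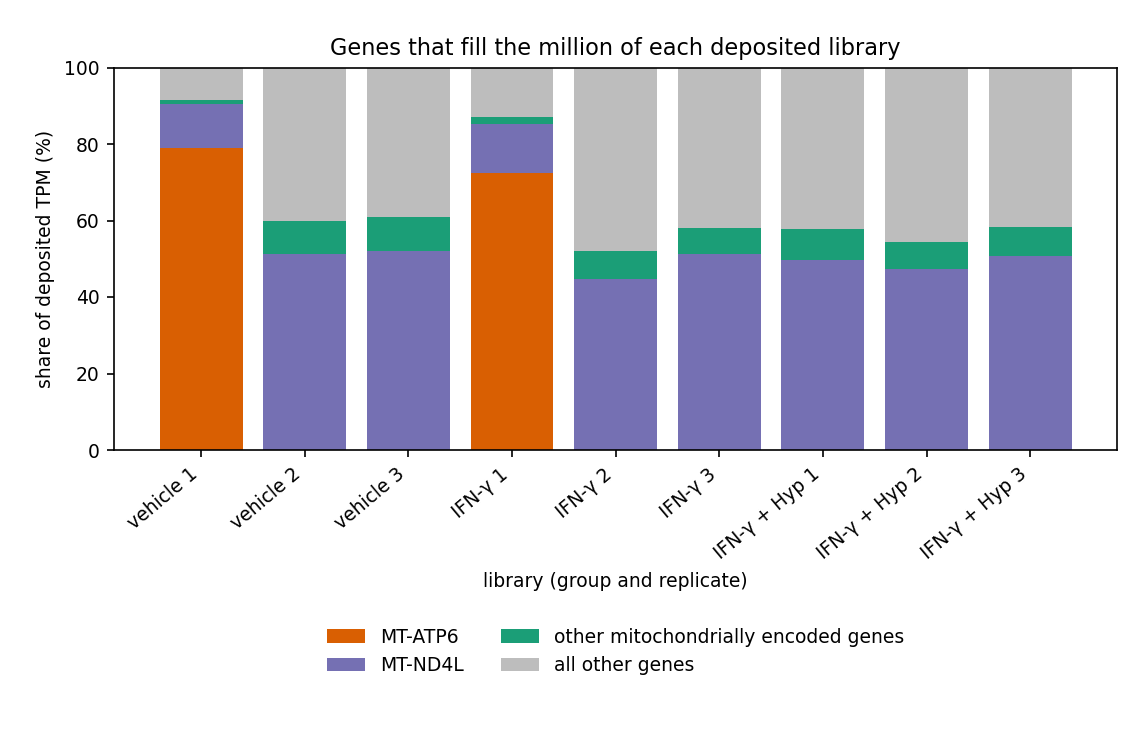
Share of each library's total TPM (percent) taken by MT-ATP6, MT-ND4L, other mitochondrial genes and all other genes. Vehicle 1 and IFN-γ 1, where MT-ATP6 took 78.9% and 72.4%, have the lowest median-of-ratios factors, 0.235 and 0.454 (not drawn).

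After rescaling, Pearson's r across genes, which are not independent replicates, was 0.965 to 0.980 for the 9 pairs within groups. It was 0.956 to 0.966 between the IFN-γ libraries with and without hydroxyproline, a range that overlaps the first, and 0.861 to 0.884 between vehicle and the other libraries. The median SE of a log2 fold change was 0.107 after rescaling and 0.630 on the deposited scale. On the deposited scale the median log2 fold change over all genes was 0.35 for IFN-γ against vehicle, 0.29 for hydroxyproline with IFN-γ against IFN-γ and 0.66 for hydroxyproline with IFN-γ against vehicle. After rescaling it was -0.02, -0.00 and -0.02.

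IFN-γ against vehicle asks what IFN-γ alone did in these cells. IFN-γ raised genes of antiviral defence, antigen presentation, chemokines, lysosomes and macrophage identity, and lowered genes of immature myeloid granules, the cell cycle and the ribosome. The lysosome and immature myeloid lists were not called with an estimated correlation (adjusted p = 0.185 and 0.0801). The largest rise was IFI27, an interferon-stimulated gene, from 1.57 ± 0.29 to 891 ± 37.4 rescaled TPM (mean ± SD, n = 3). It was followed by GBP1, an interferon-induced GTPase, from 0.324 ± 0.048 to 250.2 ± 4.34, and CXCL10, a T cell-attracting chemokine, from 0.471 ± 0.074 to 238 ± 19.5. The largest fall was CTSG, the granule protease cathepsin G, from 1276 ± 64.9 to 43.7 ± 13.1. CD274, which encodes the checkpoint ligand PD-L1, rose from 0.0638 ± 0.075 to 9.23 ± 0.63.

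The log2 fold changes of these genes were 8.44 for IFI27 (SE 0.10), 7.57 for GBP1 (SE 0.06), 7.34 for CXCL10 (SE 0.08) and -4.88 for CTSG (SE 0.18). The other genes with the largest rises were GBP5 and the cytokine gene IL32, both by 6.80, and IFI30, a lysosomal thiol reductase, by 6.43. IFI30 was erratic: it was listed at 0 in all 3 vehicle libraries and stood at 120 ± 125 rescaled TPM with IFN-γ (SE of the log2 fold change 0.90). The other largest falls were MS4A6A (-4.72), CA2, which encodes carbonic anhydrase II (-4.65), MS4A3 (-4.59), the granule protease gene PRTN3 (-3.98) and ADAM15 (-3.70, SE 1.08), a membrane protease. The adjusted p of ADAM15 was 0.0179, and 0.0984 without vehicle 1 and IFN-γ 1. SERPINB10, a serpin of blood cells named by the rule on the deposited scale, fell by 3.66 and was listed at 0 in all 3 IFN-γ libraries.

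In all, 6082 of 10387 genes were called, 3016 higher and 3066 lower, of which 1660 changed by at least 1 on the log2 scale. The groups did not overlap in 6794 genes (65.4%), where chance gives 10%, and in 991 (9.09%) on the deposited scale. The designed fit on deposited values called 508 of 10902 genes, 445 higher and 63 lower, of which 479 were also called after rescaling, none in the opposite direction. Over the other scalings the share of called genes that were higher ran from 47.2% to 65.1%, and was 49.6% after the median-of-ratios rescaling, so how many genes rose and how many fell depends on the scaling.

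Interferon genes led the rise. Of the IFN-γ response list, 32 of 35 tested members rose and 1 fell, with a median log2 fold change of 3.22 (camera adjusted p = 6.03e-17). Members included the transcription factor IRF1 (5.00), from 3.58 ± 0.44 to 145 ± 6.78. The member that fell was IRF8 (-1.07), a myeloid transcription factor. All 28 of the type I interferon-stimulated genes rose (median 2.58, adjusted p = 9.13e-19), among them the antiviral genes MX1 (4.25) and OAS1 (3.74). IDO1, which breaks down tryptophan, rose by 3.34 from 0.012 ± 0.011 to 9.28 ± 0.76 rescaled TPM. Counts adjusted over the list alone were equal to those over all genes in these and all lists below unless given.

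Antigen presentation rose with them. Of the MHC class II list, 12 of 14 rose and 1, the regulator RFXAP (-0.45), fell (median 2.36, adjusted p = 2.79e-06). HLA-DRA, a class II chain, rose by 5.94 and HLA-DPA1 by 4.48, and their master regulator CIITA by 1.14, from 0.0534 ± 0.052 to 1.32 ± 0.17 rescaled TPM. Of the MHC class I list, 16 of 17 rose (median 2.30, adjusted p = 6.89e-10), including the peptide transporter TAP1 (5.53) and the immunoproteasome subunit PSMB9 (4.40). Reads of HLA genes may be shared between similar genes, so single members are less certain than the lists. Among checkpoint and costimulatory genes, 11 of 16 rose, with CD274 by 3.27 (SE 0.08, adjusted p = 1.74e-08), CD40 by 2.63 and PDCD1LG2, which encodes PD-L2, by 1.35. One, LILRB4 (-0.68), fell. The list was called at adjusted p = 0.000399, with adjusted p = 0.110 with an estimated correlation.

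Chemokines and cytokines rose in 18 of 21 (19 adjusted over the list alone), and IL18 fell (-1.01), with a median of 1.81 (adjusted p = 3.10e-08). CXCL9 and CXCL11, T cell-attracting chemokines, rose by 5.86 and 5.27. NF-κB targets rose in 17 of 18 (median 1.57, adjusted p = 3.88e-07), with the survival gene BCL2A1 by 3.21 and TNFAIP2 by 2.78. The other, REL (-0.22), was called lower at adjusted p = 0.0362. That call was lost without vehicle 2, vehicle 3, IFN-γ 2 or IFN-γ 3, with adjusted p up to 0.130.

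Autophagy genes rose in 22 of 34 and fell in 1, the protease gene ATG4C (-0.43), with a median of 0.48 (adjusted p = 0.000119). The cargo receptors SQSTM1, which encodes p62, and OPTN rose by 2.41 and 3.04, and MAP1LC3B, which encodes the autophagosome marker LC3B, by 1.80. The call of ATG4C was lost without vehicle 2 (adjusted p = 0.0559). Lysosome genes rose in 20 of 32, including the cathepsins CTSL (2.96) and CTSD (2.67), and fell in 3, among them the hydrolases GLA (-0.42) and GUSB (-0.19). The call of GUSB was lost in 7 of the 9 fits with 1 library left out, with adjusted p up to 0.113. For the lysosome list camera gave adjusted p = 0.000163, with adjusted p = 0.185 with an estimated correlation.

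Of the stress lists, those of NRF2, ATF4 and the unfolded protein response rose as well. NRF2 targets rose in 19 of 20 (median 1.11, adjusted p = 2.80e-08), with FTH1, the ferritin heavy chain, from 174 ± 15.3 to 2200.4 ± 55.4 rescaled TPM and NQO1, a quinone reductase, by 2.80. Targets of ATF4, the regulator of the response to amino acid shortage, rose in 25 of 40 (median 0.56, adjusted p = 3.77e-06), among them GDF15 (4.46) and ATF3 (2.71). The 3 that fell were PHGDH (-0.89), EPRS1 (-0.31) and ALDH1L2 (-0.23). The call of PHGDH was lost in 6 of the 9 fits with 1 library left out, with adjusted p up to 0.140, and that of ALDH1L2 without vehicle 2 or IFN-γ 1, up to 0.102. ASNS, asparagine synthetase, did not pass the test (-0.75, adjusted p = 0.504), and its vehicle libraries read 0.871, 14.5 and 0.913 rescaled TPM. Genes of the unfolded protein response rose in 16 of 23, with the chaperone HSPA5 by 1.88 (median 0.63, adjusted p = 0.000627).

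Growth genes fell. The cell cycle list fell in 26 of 35, with MCM2, a replication helicase subunit, by 1.98 and RRM2, a ribonucleotide reductase subunit, by 1.81, and rose in 1, AURKA (0.31). Its median was -0.92 (adjusted p = 3.10e-08). MYC and ribosome biogenesis genes fell in 20 of 27 (median -0.63, adjusted p = 3.50e-06), including nucleolin (NCL, -1.34) and fibrillarin (FBL, -1.19). The exception was PNO1 (0.37), whose call was lost without vehicle 3 or IFN-γ 2, with adjusted p up to 0.0610. Cytosolic ribosomal protein genes fell in 31 of 32 (median -0.97, adjusted p = 4.81e-10), with RPL5 from 2536 ± 221 to 586 ± 55.3 rescaled TPM and RPL4 by 1.33. Cholesterol synthesis genes fell in 14 of 21, with FDFT1, squalene synthase, by 1.23 (median -0.56, adjusted p = 0.000222), and adjusted p = 0.111 with an estimated correlation. Mitochondrially encoded genes fell in 7 of 11, MT-CYB by 0.68 (median -0.60, adjusted p = 0.0263), with adjusted p = 0.430 with an estimated correlation. That list was no longer called without IFN-γ 1 or IFN-γ 2 (adjusted p up to 0.0640).

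Macrophage differentiation genes rose in 15 of 21 (median 0.96, adjusted p = 0.000151), with CD14, the lipopolysaccharide co-receptor, from 3.50 ± 0.68 to 121 ± 5.73 rescaled TPM. The 3 that fell were LYZ (-1.21), CSF1R (-0.89) and CD4 (-0.42). Immature myeloid genes fell in 10 of 13 (median -2.49, adjusted p = 0.000275, with adjusted p = 0.0801 with an estimated correlation), and HOXA9 (0.80) and CEBPE (0.63) rose.

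The remaining lists moved both ways and were not called. Proline and hydroxyproline metabolism had 4 rises and 5 falls among 13 tested genes (adjusted p = 0.886). The transaminases GOT1 (1.04) and GOT2 (0.43), PEPD (0.79), which releases proline from dipeptides, and the amino acid transporter SLC36A1 (0.51) rose. OAT (-0.79), PYCR3 (-0.70), GRHPR (-0.66), ALDH18A1 (-0.52) and P4HA1 (-0.27) fell. The calls of GRHPR and P4HA1 were lost in 8 and 3 of the 9 fits with 1 library left out, with adjusted p up to 0.153 and 0.0548. The first enzymes of proline and hydroxyproline breakdown, PRODH and PRODH2, were too low to test: PRODH stood at 0.0057 rescaled TPM or less in each library, PRODH2 was listed at 0 in all 9, as was HOGA1, and ALDH4A1 ran from 0 to 0.341. PYCR1, which makes proline, did not pass the test (-0.16, adjusted p = 0.279). Hypoxia targets had 6 rises and 8 falls of 18 (adjusted p = 0.788), glycolysis 5 and 8 of 18 (adjusted p = 0.886), and nuclear oxidative phosphorylation 5 and 11 of 36 (4 and 9 adjusted over the list alone, adjusted p = 0.248). Hyperosmotic stress genes had 3 and 3 of 7 (adjusted p = 0.892), p53 targets 7 and 5 of 17 (adjusted p = 0.403), and collagen and matrix genes 3 and 2 of 10 (adjusted p = 0.763). Median and mean differed in sign for hypoxia targets (-0.11 and 0.04), glycolysis (-0.07 and 0.09) and hyperosmotic stress genes (-0.05 and 0.01).

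Of the 26 lists, 19 were called, 13 up and 6 down, and 14 with an estimated correlation. The designed fit on deposited values also called 13 up and 6 down, but 0 with an estimated correlation. By gene it called 28 of 35 members of the IFN-γ response list and 24 of 27 of the type I list, all higher, but 0 of 35 of the cell cycle list, 0 of 32 of the ribosomal protein list and 0 of 23 of the unfolded protein response list. Fry on rescaled values called 22 in 1 direction and all 26 as changed in either.

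**Figure D2:**
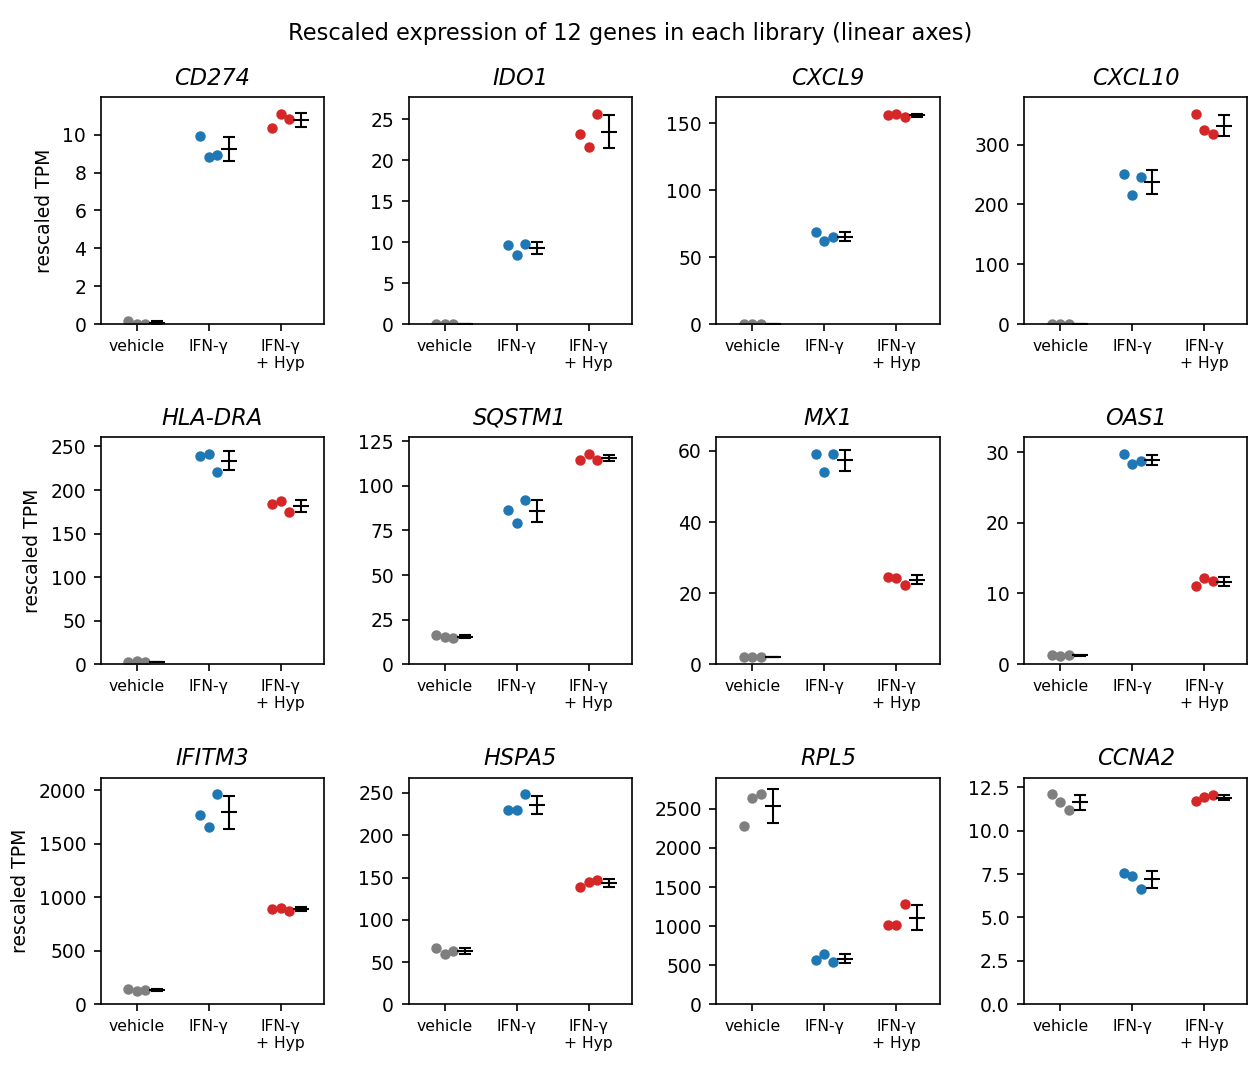
Rescaled TPM of 12 genes in each of the 9 libraries (points, linear axes) with the mean ± SD of each group of 3 beside them. CD274 stood at 0.0638, 9.23 and 10.8 in the 3 groups, and IDO1 at 0.012, 9.28 and 23.5, while MX1 stood at 2.06, 57.4 and 23.7.

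Hydroxyproline with IFN-γ against IFN-γ asks what hydroxyproline adds when IFN-γ is present in both groups. The labels give vehicle at 2% v/v for the IFN-γ libraries and no vehicle content for those with hydroxyproline. A difference in vehicle therefore cannot be told apart from hydroxyproline here. With hydroxyproline the type I interferon-stimulated genes and genes of the unfolded protein response were lower, and genes of the ribosome and the cell cycle and a set of chemokines were higher. The ribosomal protein and chemokine lists were not called with an estimated correlation (adjusted p = 0.0794 and 0.176). MX1 fell from 57.4 ± 2.91 to 23.7 ± 1.25 rescaled TPM and HSPA5 from 236 ± 10.6 to 144 ± 4.74. RPL5 rose from 586 ± 55.3 to 1105 ± 160, IDO1 from 9.28 ± 0.76 to 23.5 ± 2.01, and CXCL9 from 65.3 ± 3.47 to 156 ± 1.11. The change in CD274, from 9.23 ± 0.63 to 10.8 ± 0.36, did not pass the test (log2 fold change 0.20, SE 0.08, adjusted p = 0.116), although every library with hydroxyproline was above every library without it. It did not pass under any of the alternatives run.

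In all, 1473 of 10387 genes were called, 678 higher and 795 lower, of which 82 changed by at least 1 on the log2 scale. The share of called genes that were higher was 46.0%, and 30.4% to 44.7% over TMM, quantile and non-mitochondrial scaling. The groups did not overlap in 3624 genes (34.9%), where chance gives 10%, and in 984 (9.03%) on the deposited scale. These calls rest on the rescaling: the designed fit on deposited values called 26 of 10902 genes, 18 higher and 8 lower, 10 of them also called after rescaling, and gave adjusted p up to 0.999 for genes named here. On rescaled values the count was 883 without IFN-γ 1, 805 without hydroxyproline library 1, 830 without hydroxyproline library 2, and 692 without vehicle 1 and IFN-γ 1, of which 647 were among the 1473. Deposited values without vehicle 1 and IFN-γ 1 gave 97 higher and 391 lower.

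The largest rises were CMC2 (2.68, SE 0.59), a factor for cytochrome oxidase, and INHBA (1.97, SE 0.09), an activin subunit, from 0.435 ± 0.096 to 4.62 ± 0.65 rescaled TPM. They were followed by SYMPK (1.88), a scaffold of mRNA 3′ processing, MRPS33 (1.83), a mitochondrial ribosomal protein, NOP53 (1.77), a ribosome biogenesis factor, and POMGNT1 (1.71), a glycosyltransferase. The largest falls were WBP1 (-2.82, SE 0.12), from 6.63 ± 0.45 to 0.0831 ± 0.14 rescaled TPM, and NFE2 (-1.91, SE 0.09), a hematopoietic transcription factor. WBP1 was listed at 0 in hydroxyproline libraries 1 and 2 and stood at 0.249 in library 3, so its fall may be a failed estimate. Then came the integrin gene ITGAL (-1.75), SYTL1 (-1.66), MOV10 (-1.52), an RNA helicase, and S100A4 (-1.37), a calcium-binding protein, from 246 ± 12 to 94.9 ± 11.1. CMC2, SYMPK, ITGAL and MOV10 were erratic between libraries. Their calls were lost in 5, 4, 5 and 5 of the 9 fits with 1 library left out, with adjusted p up to 0.0659, 0.0716, 0.0890 and 0.0972. POMGNT1 had adjusted p = 0.0542 without vehicle 1 and IFN-γ 1. The rule applied to the designed fit also named HPCAL1, CD33, CARM1 and PCDHA10, whose adjusted p after rescaling was 0.131, 0.0702, 0.158 and 0.0652.

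Interferon-stimulated genes were the strongest group. Of the type I list, 25 of 28 tested members fell (26 adjusted over the list alone) and none rose. The median was -0.80 (camera adjusted p = 3.38e-24, 0.00226 with an estimated correlation). CMPK2 fell by 1.29, MX1 and OAS1 by 1.24, and IFIT2 by 1.06. IFI27 fell from 891 ± 37.4 to 407 ± 26.7 rescaled TPM. Of the IFN-γ response list, 10 of 35 fell (11 adjusted over the list alone) and 1, IDO1 (1.25, SE 0.08), rose (3 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.00277, 0.0455 with an estimated correlation). The members that fell included IRF7 (-1.21) and STAT2 (-0.86), transcription factors of the type I response, and IFITM3 (-1.01) and IFITM2 (-1.28), membrane proteins that block virus entry. IFITM genes are close copies and may share reads. IRF1 (-0.14, adjusted p = 0.332) did not pass the test.

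Of the MHC class II list, 3 of 14 fell (4 adjusted over the list alone): CD74 (-0.66), the invariant chain, HLA-DRA (-0.36), from 234 ± 10.9 to 182 ± 6.89 rescaled TPM, and HLA-DPA1 (-0.24). The list was not called (adjusted p = 0.0542), and CIITA stood at 1.32 ± 0.17 and 1.37 ± 0.19 (adjusted p = 0.839). Of the MHC class I list, 4 of 17 fell (6 adjusted over the list alone), among them HLA-C (-0.39), TAP2 (-0.37) and PSME1 (-0.25). It was called (median -0.20, adjusted p = 0.00611), with adjusted p = 0.168 with an estimated correlation. None of these 6 single-gene calls held in all 9 fits with 1 library left out. The call of HLA-C was lost without hydroxyproline library 1 or 2 or IFN-γ 1 (adjusted p up to 0.0582). That of HLA-DRA was lost without IFN-γ 1, IFN-γ 2, or hydroxyproline library 1 or 3 (up to 0.0639). The others were lost in 6 (CD74, up to 0.0937), 7 (HLA-DPA1, up to 0.122), 8 (TAP2, up to 0.134) and 9 fits (PSME1, up to 0.115). Of the checkpoint list, LILRB2 alone rose (0.49) and none fell of 16 (2 and 2 adjusted over the list alone, adjusted p = 0.881). PDCD1LG2 stood at 1.63 ± 0.27 and 1.63 ± 0.45 rescaled TPM (adjusted p = 0.974). The median of this list was 0.03 and its mean -0.02.

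Chemokines and cytokines rose in 8 of 21 (10 adjusted over the list alone) and fell in 2, with a median of 0.44 (adjusted p = 0.000642), and adjusted p = 0.176 with an estimated correlation. CXCL9 rose by 1.25 (SE 0.06), CXCL10 by 0.48, CCL3 by 1.01, CCL5 by 0.64, TNF by 0.75, CXCL8 by 1.1, IL18 by 0.90 and IL1B by 0.38. TNFSF13B (-1.01), which encodes the B cell factor BAFF, and TNFSF10 (-0.40), which encodes TRAIL, fell. The calls of CXCL8 and IL1B were each lost in 7 of the 9 fits with 1 library left out, with adjusted p up to 0.128 and 0.115. NF-κB targets rose in 4 of 18 (7 adjusted over the list alone), IER3 (0.92), NFKBIA (0.60), RELB (0.55) and TNFAIP2 (0.33), with a median of 0.21 (adjusted p = 0.00177), and adjusted p = 0.192 with an estimated correlation. The call of NFKBIA was lost in 5 of those fits (up to 0.0720) and that of IER3 without hydroxyproline library 1 or 2 (up to 0.0573).

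Genes of the unfolded protein response fell in 11 of 23 (16 adjusted over the list alone) and rose in none. The median was -0.41 (adjusted p = 7.87e-08, 0.0150 with an estimated correlation). DNAJB9, a chaperone induced by XBP1, fell by 1.15, the translocon subunit SEC61B by 0.99 and SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, by 0.72. ATF4 targets fell in 10 of 40 (14 adjusted over the list alone), with CHAC1 by 0.72, and rose in 1, ATF3 (0.44). Camera gave a median of -0.18 and adjusted p = 0.00642, with adjusted p = 0.168 with an estimated correlation. ASNS did not pass the test (0.65, adjusted p = 0.684). Cholesterol synthesis genes fell in 7 of 21 (11 adjusted over the list alone), with MSMO1 by 0.64 and FDFT1 by 0.42 (median -0.31, adjusted p = 7.44e-05), and adjusted p = 0.164 with an estimated correlation.

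Growth genes were higher. Ribosomal protein genes rose in 14 of 32 (21 adjusted over the list alone), with RPL5 by 0.91, RPS4X by 0.73 and RPL4 by 0.68, and none fell. The median was 0.38 (adjusted p = 2.15e-11), with adjusted p = 0.0794 with an estimated correlation. Cell cycle genes rose in 12 of 35 (15 adjusted over the list alone), with CCNA2, cyclin A2, from 7.19 ± 0.51 to 11.9 ± 0.17 rescaled TPM and AURKB by 0.65. The median was 0.31 (adjusted p = 8.60e-07, 0.0150 with an estimated correlation). Not every member that IFN-γ lowered returned. MCM2 stood at 4.84, 5.14 and 4.58 rescaled TPM with IFN-γ and at 5.54, 5.25 and 4.78 with hydroxyproline. With vehicle it stood at 23.4, 21.3 and 21.8. MYC and ribosome biogenesis genes rose in 8 of 27 (10 adjusted over the list alone), with NPM1 by 0.68 and FBL by 0.62 (median 0.21, adjusted p = 1.18e-05, 0.0150 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 11, MT-ND1 (0.40) and MT-CYB (0.39), calls lost in 6 and 5 of the 9 fits with 1 library left out (adjusted p up to 0.115 and 0.0914). The list was called at adjusted p = 0.0218, with adjusted p = 0.533 with an estimated correlation. Without IFN-γ 1, IFN-γ 2 or hydroxyproline library 3 it was not called (up to 0.122).

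The autophagy list was not called (median -0.11, adjusted p = 0.0542). SQSTM1 rose by 0.43 (SE 0.07, adjusted p = 0.00898), from 85.9 ± 6.39 to 116 ± 1.85 rescaled TPM. It was the only member called when adjusted over the list alone. Over all genes 2 of the 34 fell, ULK1 (-0.29) and ATG101 (-0.36), which encode parts of the initiating kinase complex, but their calls were lost in 5 and 8 of the 9 fits with 1 library left out (adjusted p up to 0.0794 and 0.141). MAP1LC3B did not pass the test (-0.18, adjusted p = 0.356). Lysosome genes rose in 4 of 32, CTSL (0.64), CTSH (0.56), ATP6AP1 (0.38) and ATP6V1H (0.27), and fell in 3, TPP1 (-0.52), CTSS (-0.31) and HEXA (-0.24), with 4 and 4 adjusted over the list alone (adjusted p = 0.728 for the list). Of these the calls of ATP6AP1, ATP6V1H, CTSS and HEXA were lost in 6, 8, 5 and 6 of the 9 fits, with adjusted p up to 0.102, 0.128, 0.0898 and 0.0829.

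Of 13 tested genes that handle proline and hydroxyproline none rose, and only P4HB (-0.34), the protein disulfide isomerase subunit of prolyl 4-hydroxylase, fell (adjusted p = 0.944 for the list), a call lost without IFN-γ 3 or hydroxyproline library 1 or 3 (up to 0.0693). PYCR1 did not pass the test (0.21, adjusted p = 0.290). NRF2 targets went both ways (adjusted p = 0.395): HMOX1, heme oxygenase, rose from 2.75 ± 0.77 to 8.02 ± 0.53 rescaled TPM and FTH1 by 0.55, while NQO1 (-0.89), GCLM (-0.36), PGD (-0.34), GSR (-0.33) and SLC7A11 (-0.23) fell. Counts were 2 and 5 of 20, and 3 and 7 adjusted over the list alone. The calls of PGD, GSR and SLC7A11 were lost in 3, 3 and 7 of the 9 fits, with adjusted p up to 0.0560, 0.0576 and 0.120. Hyperosmotic stress genes, included because the solute was at 40 mM, gave 2 rises, SGK1 (0.72) and AKR1B1 (0.26), and 1 fall, the betaine transporter SLC6A12 (-0.52), among 7 (2 and 3 adjusted over the list alone, adjusted p = 0.641). The call of AKR1B1 was lost in 7 of the 9 fits (up to 0.124).

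Macrophage differentiation genes rose in 4 of 21, NR1H3 (0.69), C1QB (0.51), LYZ (0.27) and FCGR2A (0.23), and fell in 5, SIGLEC1 (-1.21), ITGAX (-0.55), AXL (-0.46), ITGAM (-0.41) and CEBPB (-0.35), with 5 and 5 adjusted over the list alone (adjusted p = 0.881). NR1H3, C1QB, LYZ, FCGR2A, ITGAM and CEBPB lost their calls in 4, 4, 7, 8, 5 and 8 of the 9 fits with 1 library left out, with adjusted p up to 0.0842, 0.0830, 0.136, 0.110, 0.0601 and 0.145. Of 13 immature myeloid genes CTSG rose (0.82) and RNASE2 fell (-0.69), with 3 and 1 adjusted over the list alone (adjusted p = 0.881), and the call of CTSG was lost in 5 fits (up to 0.0669). Hypoxia targets and glycolysis shared 1 rise, HK2 (0.34), of 18 each (adjusted p = 0.921 and 0.818), lost in 4 fits (up to 0.0846). Collagen and matrix genes had 1 rise of 10, MMP9 (0.45, adjusted p = 0.937 for the list), lost in 7 (up to 0.123) and not called when adjusted over the list alone. Of 17 p53 targets PMAIP1 (-0.57) and PHLDA3 (-0.61) fell (adjusted p = 0.728 for the list). Of 36 nuclear oxidative phosphorylation genes NDUFA9 (-0.42) and COX6A1 (-0.24) fell (1 adjusted over the list alone, adjusted p = 0.959), the first not called without hydroxyproline library 1 (0.0506) and the second in 6 of the fits (up to 0.103). Median and mean differed in sign for the macrophage list (-0.07 and 0.02) and the p53 targets (-0.02 and 0.04).

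**Figure D3:**
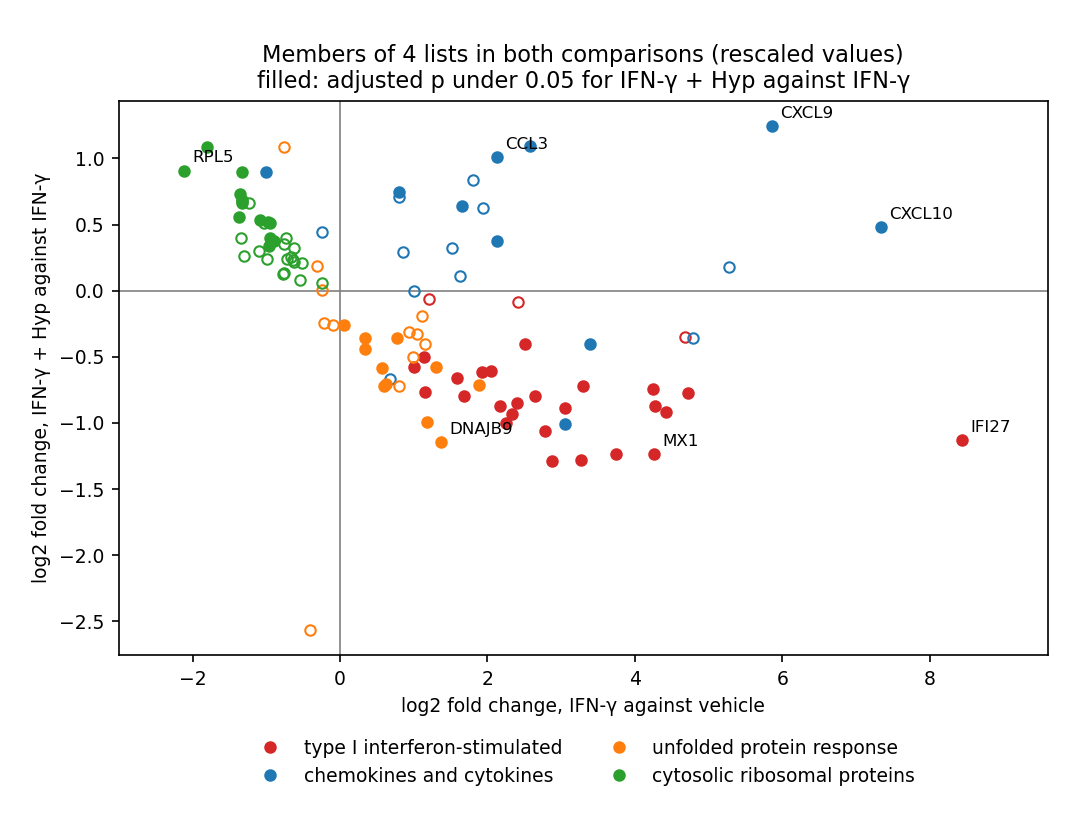
Log2 fold change of each tested member with IFN-γ against vehicle (x) and with hydroxyproline and IFN-γ against IFN-γ (y) for 4 lists, filled where the member passed the test in the second comparison. Of the type I interferon-stimulated genes 25 of 28 are filled and lie below 0, and of the ribosomal protein genes 14 of 32 are filled and lie above 0.

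Of the 26 lists, 12 were called, 6 up and 6 down. The 5 that held with an estimated correlation were the 2 interferon lists, the unfolded protein response, the cell cycle and MYC and ribosome biogenesis. Fry called 14 in 1 direction and 23 as changed in either. The designed fit on deposited values called 9, 6 up and 3 down, and 0 by an estimated correlation (each adjusted p = 0.998) or by either fry test. By gene it called 0 of 27 members of the type I list, 0 of 23 of the unfolded protein response list, 0 of 22 chemokines and cytokines, 0 of 32 of the ribosomal protein list and 0 of 35 of the cell cycle list. It did not call the IFN-γ response, MHC class I and ATF4 lists (adjusted p = 0.181, 0.408 and 0.228), whose medians there were 0.29, 0.23 and 0.23 beside 0.29 for all genes.

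By covariance the hydroxyproline effect ran partly against the IFN-γ effect. Among genes raised by IFN-γ, 513 fell and 163 rose with hydroxyproline. Among genes lowered by IFN-γ, 387 rose and 129 fell. Both comparisons use the IFN-γ libraries, which by itself gives opposite effects. In simulations of unchanged groups the covariance across genes was -0.0313 (SD 0.00586), against -0.107 observed, a difference of -0.0753. The correlation was -0.330, against -0.491 simulated, but these do not compare, since an IFN-γ effect adds variance that unchanged groups lack. On the deposited scale the observed covariance was below 0 as well, -0.0788, against -0.186 simulated, a difference of 0.107. The simulated noise there takes in the shift of vehicle 1 and IFN-γ 1 as if independent between genes. Most genes share that shift, which a covariance across genes largely removes, so the sign of this difference decides nothing. Of 117 members of the interferon, MHC, checkpoint and chemokine lists that IFN-γ raised, 44 (37.6%) fell and 9 (7.69%) rose with hydroxyproline. The type I list, with 28 raised, gave 25 of these 44 falls, so the share is not common to all the lists. Checkpoint genes gave 0 falls and 1 rise of 11, and chemokines 2 falls and 7 rises of 18. Over all 3016 genes raised by IFN-γ, 513 fell and 163 rose.

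**Figure D4:**
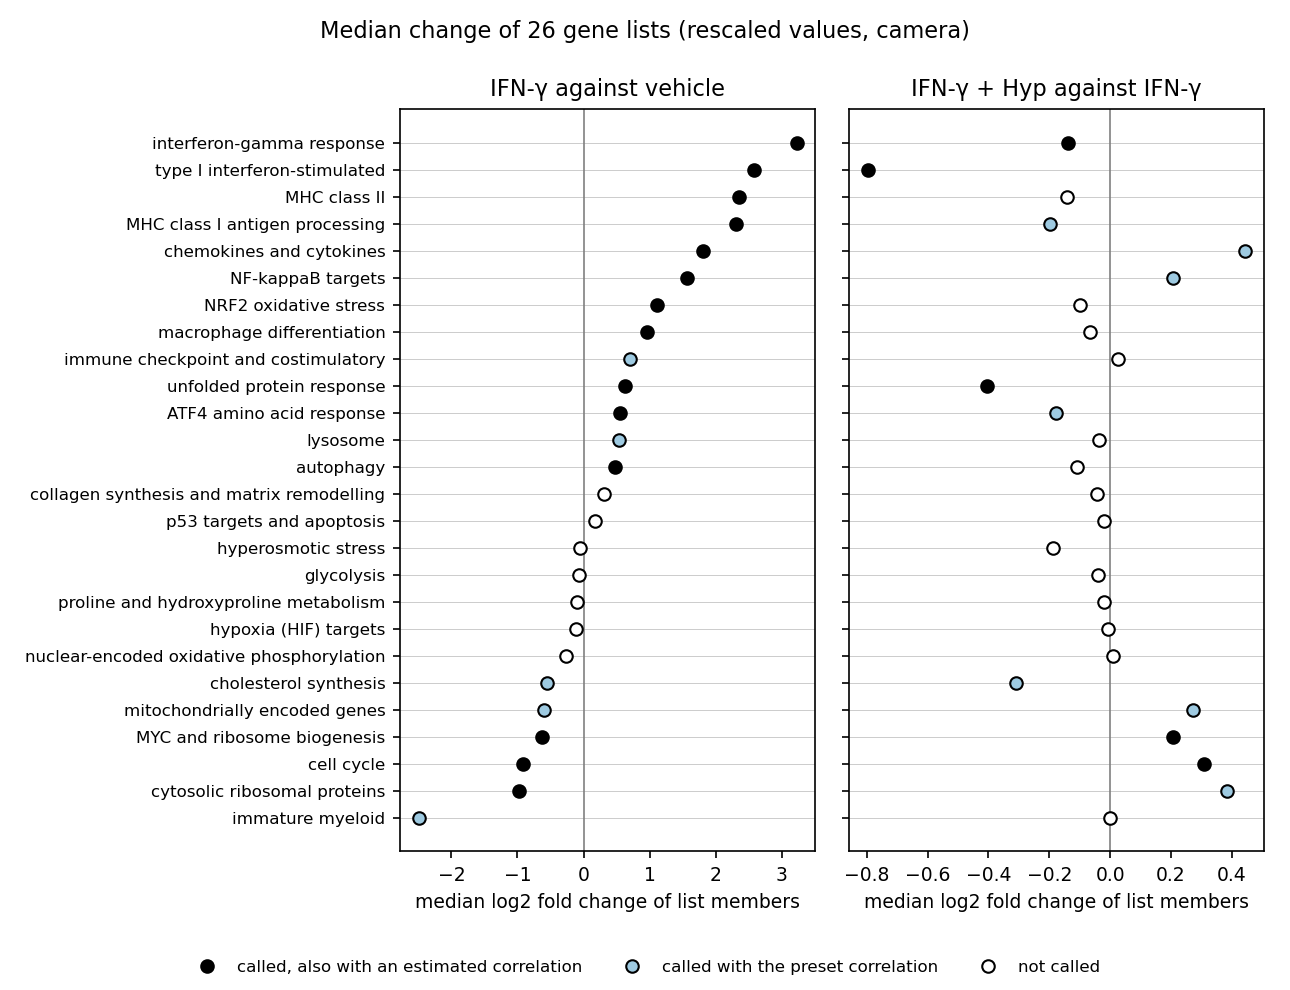
Median log2 fold change of the tested members of 26 lists for IFN-γ against vehicle and for hydroxyproline with IFN-γ against IFN-γ. Black points were called by camera with the preset and an estimated correlation, light blue ones with the preset alone and white ones not, and the type I list lies at 2.58 and -0.80.

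Hydroxyproline with IFN-γ against vehicle gives the effect of both together. Of the 6 largest rises and the 6 largest falls with IFN-γ alone, 5 each were among the 6 largest here as well. CXCL10 rose by 7.82, GBP1 by 7.43, IFI27 by 7.31, CXCL9 by 7.10 and GBP5 by 6.98. CXCL10 reached 332 ± 17.4 rescaled TPM from 0.471 ± 0.074 and CD274 10.8 ± 0.36 from 0.0638 ± 0.075. IFI30, listed at 0 with vehicle, was again erratic (6.97, SE 0.90). The largest falls were MS4A6A (-4.76), MS4A3 (-4.27), CA2 (-4.23), CTSG (-4.05), RNASE3 (-3.61), an eosinophil granule ribonuclease, and PRTN3 (-3.56).

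Of 10387 genes, 5714 were called, 2794 higher and 2920 lower, and 1402 of them changed by at least 1 on the log2 scale. The share of called genes that were higher was 48.9%, and 46.0% to 60.9% over TMM, quantile and non-mitochondrial scaling. The groups did not overlap in 6678 genes (64.3%), where chance gives 10%, and in 5070 (46.5%) on the deposited scale. The designed fit on deposited values called 824 of 10902, 774 higher and 50 lower, of which 726 were also called after rescaling. Across genes the effect of both followed that of IFN-γ alone (covariance 0.681, against 0.0330 simulated for unchanged groups with shared vehicle libraries).

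All 28 type I interferon-stimulated genes were above vehicle with both, with a median of 1.79 (camera adjusted p = 6.17e-17), and 31 of 35 of the IFN-γ response list rose and 2, IRF8 (-0.81) and IRF5 (-0.37), fell, with a median of 2.73 (adjusted p = 6.17e-17). IRF1 rose by 4.86 and IDO1 by 4.59. The MHC class II list rose in 12 of 14 (median 2.34, adjusted p = 2.63e-06), with HLA-DRA by 5.58 and CIITA by 1.17, and fell in 2, RFXAP (-0.63) and RFX5 (-0.32). The class I list rose in 16 of 17 (median 1.91, adjusted p = 3.70e-10). Chemokines and cytokines rose in 18 of 21 (median 2.30, adjusted p = 3.64e-10) and NF-κB targets in 17 of 18 (median 1.95, adjusted p = 3.61e-08), and none fell (for NF-κB targets 1 adjusted over the list alone). CD274 rose by 3.47 (SE 0.08) and PDCD1LG2 by 1.34. Of 16 checkpoint genes 9 rose and 1, LILRB4 (-0.39), fell (10 and 2 adjusted over the list alone), with the list called at adjusted p = 0.000601, and adjusted p = 0.120 with an estimated correlation. SQSTM1 rose by 2.84 and MAP1LC3B by 1.62, with 19 autophagy genes of 34 higher and 3 lower, ATG4C (-0.40), GABARAPL2 (-0.37) and ATG4B (-0.23) (median 0.32, adjusted p = 0.000601). PYCR1 (0.05, adjusted p = 0.774) and ASNS (-0.10, adjusted p = 0.934) did not pass the test.

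Ribosomal protein genes fell in 25 of 32 (26 adjusted over the list alone), with a median of -0.55 (adjusted p = 6.62e-07), and adjusted p = 0.0957 with an estimated correlation. The cell cycle list fell in 21 of 35 and rose in 2, AURKA (0.68) and CCNB1 (0.47) (3 rises adjusted over the list alone), with a median of -0.55 (adjusted p = 0.000134). The MYC list fell in 17 of 27 and rose in 1, PNO1 (0.66), with a median of -0.46 (adjusted p = 0.000601). Cholesterol synthesis genes fell in 17 of 21 (median -0.91, adjusted p = 1.99e-06), with adjusted p = 0.0597 with an estimated correlation. Genes of the unfolded protein response rose in 8 of 23, fell in 3, SDF2L1 (-2.97, SE 0.77), CALR (-0.35) and PDIA6 (-0.20), and were not called as a list (median 0.08, adjusted p = 0.301). NRF2 targets rose in 16 of 20 (median 1.06, adjusted p = 5.67e-08) and macrophage genes in 16 of 21 (median 1.19, adjusted p = 8.01e-05), where CSF1R (-0.95), LYZ (-0.94) and CD4 (-0.49) fell. Of these exceptions RFX5, ATG4C, GABARAPL2, ATG4B, CALR and PDIA6 lost their calls in 3, 3, 2, 1, 3 and 6 of the 9 fits with 1 library left out, with adjusted p up to 0.0799, 0.0736, 0.0522, 0.0518, 0.0763 and 0.101. Of the 26 lists 17 were called, 12 up and 5 down, and 11 with an estimated correlation. On deposited values 16 were called, 12 up and 4 down, and 0 with an estimated correlation. By gene 28 of 35 members of the IFN-γ response list and 24 of 27 of the type I list were called there, all higher, but 0 of 35 of the cell cycle list and 0 of 32 of the ribosomal protein list. There the medians of the cell cycle, MYC and ribosomal protein lists were 0.33, 0.41 and 0.47, above 0 but below the 0.66 of all genes, and the MYC list was not called (adjusted p = 0.0613).

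The genes fixed in advance are placed as follows on GRCh38. CD274 (ENSG00000120217) lies on chromosome 9 from 5450503 to 5470566, plus strand, and IDO1 (ENSG00000131203) on chromosome 8 from 39902275 to 39928444, plus strand. SQSTM1 (ENSG00000161011) lies on chromosome 5 from 179806398 to 179838078, plus strand, CXCL9 (ENSG00000138755) on chromosome 4 from 76001275 to 76007488, minus strand, and HLA-DRA (ENSG00000204287) on chromosome 6 from 32439842 to 32445046, plus strand. Each is annotated as protein coding. With 3′ libraries the reads of a gene come mainly from the end of its last exon.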

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

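The scaling without mitochondrial genes, the omission of vehicle 1 and IFN-γ 1 together and every alternative to the rescaled values were chosen after the data were seen. Genes called for IFN-γ against vehicle, for hydroxyproline with IFN-γ against IFN-γ and for both against vehicle are given in that order. The designed fit on deposited values called 508, 26 and 824. With no filter it called 97, 9 and 393, and with a 5 TPM filter 334, 17 and 504. The median-of-ratios rescaling gave 6082, 1473 and 5714, TMM factors 6037, 1596 and 5639, and quantile normalization 6030, 1558 and 5710. Without mitochondrial genes the counts were 7221, 1673 and 6711, and without vehicle 1 and IFN-γ 1 they were 5029, 488 and 4513. With only the 6 libraries of the groups compared, IFN-γ against vehicle gave 220 genes, and with no trend hydroxyproline with IFN-γ against IFN-γ gave 2.

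The rescaled counts with a 5 TPM filter were 3340 for IFN-γ against vehicle and 3091 for both against vehicle, and fewer genes are tested there. With a log2 fold change of at least 1 they were 1660, 82 and 1402. Hydroxyproline with IFN-γ against IFN-γ gave 692 without vehicle 1 and IFN-γ 1, which leaves 7 libraries. A replicate block by the numbers of the titles gave 1103, 73 and 1963 genes on deposited values. After rescaling, correlations between libraries of 1 number after removal of group means were -0.219 to 0.128. In both other groups at once, 0 of 9 libraries were closest to the library of their own number. Matches in 1 other group alone were not counted, so these values show no consistent pairing but do not exclude a partial one. On deposited values vehicle 1 and IFN-γ 1, both led by MT-ATP6, share the number 1, and hydroxyproline library 1 had MT-ATP6 at 0.

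With 1 library left out, deposited counts ran from 199 (without IFN-γ 3) to 1656 (without IFN-γ 1), from 9 (without hydroxyproline library 2) to 65 (without vehicle 1), and from 359 (without hydroxyproline library 2) to 1564 (without IFN-γ 1). Rescaled counts ran from 5167 to 6084, from 805 (without hydroxyproline library 1) to 1365, and from 4771 to 5822. Lists called on deposited values, 19, 9 and 16, ran over 18 to 19, 7 to 9 and 16 to 18. On rescaled values, 19, 12 and 17, they ran over 18 to 19, 11 to 13 and 17 to 17.

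With an estimated correlation 0, 0 and 0 lists were called on deposited values, with directional fry 6, 0 and 9, and with mixed fry 10 and 0 in the first pair of comparisons. On rescaled values hydroxyproline with IFN-γ against IFN-γ gave 5 with an estimated correlation and 23 with mixed fry, and both against vehicle gave 11 and 26. Fry does not compare a list with other genes, and the cause of the other differences was not tested.

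The covariance of the hydroxyproline effect and the IFN-gamma effect, less its simulated value, was 0.107 on deposited values, 0.176 and 0.0554 with pseudocounts of 0.1 and 5, 0.125 with the 5 TPM filter, and 0.0165 (without vehicle 1) to 0.240 (without IFN-γ 3) with 1 library left out. Of the covariance of the hydroxyproline effect and the IFN-gamma effect, median-of-ratios scaling turned the sign (-0.0753), as did the omission of vehicle 1 and IFN-γ 1 (-0.0744). After rescaling it was -0.114 and -0.0410 with those pseudocounts, -0.119 with the filter, -0.0652 without the 2 libraries and -0.0907 to -0.0574 with 1 left out. On deposited values the difference was thus above 0 only where vehicle 1 or IFN-γ 1 entered. With either of them in, the simulated value counts a shift shared by most genes as independent noise, so the sign decides nothing. The cause of the differences in size was not tested.

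On the deposited scale some named falls had a log2 fold change above 0, each but PDIA6 below the median of all genes there. For IFN-γ against vehicle (median 0.35) these were GUSB 0.33, EPRS1 0.26, P4HA1 0.22, CSF3R 0.22, ALDH1L2 0.17, CD4 0.088, GLA 0.083 and REL 0.055, and GUSB was 0.053 without mitochondrial genes. For hydroxyproline with IFN-γ against IFN-γ (median 0.29) they were COX6A1 0.19, PSME1 0.18, HLA-DPA1 0.17, CTSS 0.12, SLC7A11 0.12, HEXA 0.11, P4HB 0.085, GSR 0.080, PGD 0.078, HLA-DRA 0.075, CEBPB 0.070, TAP2 0.052, HLA-C 0.046, GCLM 0.038, ATG101 0.021 and TNFSF10 0.013. For both against vehicle (median 0.66) they were PDIA6 0.81, CALR 0.65, GABARAPL2 0.61, IRF5 0.53, ATG4B 0.52, LILRB4 0.49, CD4 0.37, RFX5 0.34, IRF8 0.16, ATG4C 0.12 and LYZ 0.052. No other called named gene turned. Of the lists, the medians of the IFN-γ response (0.29), MHC class I (0.23) and ATF4 (0.23) lists for hydroxyproline with IFN-γ against IFN-γ, and of the cell cycle (0.33), MYC (0.41) and ribosomal protein (0.47) lists for both against vehicle, were above 0 there, though camera, which sets a list against the other genes, kept its direction. Of the genes that had not passed the test, ASNS, CIITA, IRF1, MAP1LC3B, PDCD1LG2 and PYCR1 changed sign in 21 values. Under the alternatives 4575 values of named genes and 979 of named lists kept their direction and side of the threshold, and 715 and 30 kept their direction without passing the test; CARM1, CD33, HPCAL1 and PCDHA10, which had not passed it, did so in 13.

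A test for whole read counts (DESeq2 or edgeR), planned only if the values held whole reads, was not run. Depth is unknown, so no interval or detection floor that needs it is given. On simulated data with 200 changed genes, the rescaled fit recovered 52.1%, 80.7% and 92.7% of changes of 0.5, 1 and 2 on the log2 scale, with 3.60% of its calls false. The designed fit recovered 0%, 0% and 25.5%, with 40.7% of its calls false. Only hydroxyproline with IFN-γ against IFN-γ was simulated. The simulated values took their means and spread from the rescaled data, with independent noise. Each library was then multiplied by its real median-of-ratios factor, which the rescaling undoes. The advantage of the rescaled fit was therefore built in and is no support for choosing it.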

Other observations

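The tests of mitochondrial read assignment, of the scalings, of a weaker IFN-γ action on chemokines and of hyperosmotic stress were chosen after the result was seen.

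Markers of other cell types were low. Of 10 neutrophil markers 4 were tested, with S100A12 the highest at a mean of 9.91 rescaled TPM. With IFN-γ S100A12 rose (1.91), CXCR2 (-1.73) and CSF3R (-0.28) fell, and with hydroxyproline CSF3R fell again (-0.63). Of 15 T and NK cell markers 3 were tested, with NKG7 the highest at 5.14. IFN-γ raised GNLY (1.21) and lowered NKG7 (-0.92) and TRAC (-0.52), and hydroxyproline raised TRAC (0.80), from 0.696 ± 0.085 to 1.95 ± 0.12 rescaled TPM. None of 10 B cell markers was tested (highest CD79B, 0.611). Of 13 erythroid and megakaryocyte markers 11 were listed at 0 in all libraries, and GP9 alone was tested, which fell with IFN-γ (-0.93). Of 15 epithelial and fibroblast markers PECAM1 alone was tested, with a mean of 5.86, and it fell with hydroxyproline (-0.59). CSF3R, S100A12 and PECAM1 are also expressed by monocytic cells.

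Nearly all genes of vehicle 1 and IFN-γ 1 were listed several times lower than in the other libraries of their groups, by 5.01 and 3.45 times in their median-of-ratios factors. The tables argue against more mitochondrial RNA in these libraries. Relative to nuclear genes, 8 other mitochondrial genes had a median log2 ratio to their group of 0.133 in vehicle 1 (SD over genes 0.0822) and -0.141 in IFN-γ 1 (SD 0.102), where at least 1 was predicted. A candidate explanation is the assignment of mitochondrial reads in the quantification. MT-CO3, whose gene overlaps the end of MT-ATP6, was listed at 0 in exactly these 2 libraries and at 3218 to 4386 TPM in the other 7. MT-ATP6 stood at 788863 and 723569 TPM in the 2, so the listed amount of MT-CO3 alone falls far short of it. The test on MT-CO3 replaced one on the median ratio without mitochondrial genes (-0.0607 and 0.0118). The rescaling to a fixed total nearly fixes the outcome of that earlier test. No biological explanation other than more mitochondrial RNA was tested.

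With hydroxyproline added to IFN-γ, type I interferon-stimulated genes were lower and chemokines and cytokines higher, the latter not called as a list with an estimated correlation (adjusted p = 0.176). A scaling factor moves all genes of a library alike, apart from the pseudocount, so it can hardly make 2 lists differ. The medians of the 2 lists differed by 1.2 to 1.37 over 5 scalings. Both were called in opposite directions in each at the preset correlation. For all but quantile normalization this outcome was nearly fixed in advance, so it is no separate support. Without vehicle 1 and IFN-γ 1 both stayed called (higher adjusted p = 0.000214), though with an estimated correlation the p was 0.0225 for the type I list and 0.0878 for chemokines. A weaker IFN-γ action alone, on all of its targets alike, is argued against by the chemokines. Of 18 raised by IFN-γ, 7 rose further with hydroxyproline and 2 fell. CXCL9 rose by 1.25 (SE 0.06) and CCL5 by 0.64 (SE 0.08). Their rise is part of the pattern itself, so it is no separate support. A weaker IFN-γ action that another input outweighs at the chemokines cannot be excluded by these values. The share of all 117 raised members that rose, 7.69%, lay between the bounds of 5% and 10% set beforehand and by itself decides nothing. Still open is a weaker action on the type I genes alone, which was not tested apart from their fall. Hyperosmotic stress is open as well: 2 of 7 genes rose, where 3 or more would speak for it and 0 against it. The call of AKR1B1 was lost in 7 of the 9 fits with 1 library left out, and SLC6A12 fell by 0.52. As a hypothesis, a separate action of hydroxyproline may lower the type I genes and raise the chemokines. No library had hydroxyproline without IFN-γ, so a separate action and a changed IFN-γ response cannot be told apart here.

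Ribosomal protein, cell cycle and MYC and ribosome biogenesis genes were higher with hydroxyproline, opposite to their change with IFN-γ. The ribosomal protein list was not called with an estimated correlation (adjusted p = 0.0794). A trend with transcript length and GC content is argued against as the whole cause, since the median over the 94 members was 0.306 before and 0.301 after its removal (SD over genes 0.251). That correction was weak, since it moved genes by 0.0290 in the median and 0.171 at most. An atypical IFN-γ library is argued against, since the 3 lists stayed called at the preset correlation whichever IFN-γ library was left out (highest adjusted p = 8.54e-05). The shared IFN-γ libraries by themselves give opposite effects and stay open in part. Of 35 cell cycle genes 12 were called higher, while MCM2 and MCM3, which IFN-γ lowered, stayed near their level with IFN-γ alone. A partial return of growth with hydroxyproline may be the cause, as a hypothesis. It was not tested apart from the shared libraries, and these data hold no measure of growth itself.

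The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. On rescaled values 1 split, the real one, gave as many genes in each comparison: 6082 for IFN-γ against vehicle (highest other 2), 1473 for hydroxyproline with IFN-γ against IFN-γ (highest other 4) and 5714 for both against vehicle (highest other 3). On deposited values the real split gave 508 (highest other 314) and 824 (highest other 20), and for hydroxyproline with IFN-γ against IFN-γ 2 splits gave as many, the real one with 26 and another with 27. In the first of these the splits that put vehicle 1 and IFN-γ 1 together gave 314 and 217 genes with a vehicle library as the third, and 57 and 11 with an IFN-γ library. The cause was not tested.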
